A study of Mus musculus with 13 samples.

How the data were processed

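RNA from mouse cell lines was sequenced in 13 libraries from 2 separate experiments. In the first, 3 clones of Min6-ARX, a Min6 insulinoma (beta cell) line in which doxycycline switches on the transcription factor Arx, were sampled without doxycycline, after 3 days and after 6 days, giving 1 library per clone and time. In the second, the glucagonoma (alpha cell) line alpha-TC1 received DMSO or 10 µM of artemether, with 2 biological repeats per arm. RNA was purified on columns and libraries were made with an Illumina RNA-seq kit, per the labels' protocols.

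The deposited values are RPKM (reads per kilobase of transcript, scaled to library size) computed by the authors, with 1 row per transcript. Reads were aligned with TopHat2 2.0 to the mouse build mm10, per the submitters' processing notes. The read counter, the gene annotation and the strand setting are not given in the sources used here. In both experiments 0.0001 stands for 0. The unit was checked on the values of transcripts of known length. There 76.9% to 81.1% of low values fell within 0.15 of a whole multiple of the value of 1 read. That value was chosen as the step that best fitted these same low values, so the share is partly built in. The step size puts the depth at 22120000 to 25410000 reads in the alpha-TC1 libraries and 18670000 to 23260000 in the Min6-ARX libraries. On 6 simulated libraries this estimate erred by at most 0.64%.

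The alpha-TC1 values cover 51068 transcripts and the Min6-ARX values 26902. Rows whose names had been turned into dates (38 and 44) were left out, as were 2 Min6-ARX rows with unreadable values (Mt1 and Tpt1). The transcript row with the highest mean stood for its gene. Names with identical values in every library were merged, since reads of near-identical copies could not be told apart. This gave 21645 alpha-TC1 and 20246 Min6-ARX genes, of which 10993 and 11172 had a mean of at least 1 RPKM and were tested. Gapdh, Aldoa, Pgk1, Tpi1, Bnip3, Hspa8, Hspe1, Hspa1a, Mif and Ldha share their alpha-TC1 values with copies or pseudogenes and stand for the group. Gene positions come from GENCODE M21 on GRCm38, the assembly mm10 names.

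The design fixed before the data were examined assumed read counts. Because the values are RPKM, the branch written for normalized values was used: limma 3.58.1 in R 4.3.3 with empirical Bayes moderation and a mean-variance trend on log2(RPKM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values in the text come from this limma test or, for gene lists, from limma's camera, except where fry is named. A fold change on this scale understates the change of genes with low RPKM. Min6-ARX contrasts used all 9 libraries with the clone as a block, because libraries with the same number come from the same clonal line. As a check of the pairing, deviations from the group means correlated at 0.496 to 0.837 between libraries of the same clone. The alpha-TC1 contrast used 4 libraries with no block. The series design text calls its repeats biological; clones, and not repeat cultures of each clone, are the replicates of the Min6-ARX contrasts.

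Before the data were examined, 27 gene lists were fixed, and lists with at least 5 tested members entered camera with a preset correlation between genes of 0.01, adjusted over 22 lists per contrast. Estimated correlations and the fry test were run beside it. With estimated correlations no list passed in any contrast, and fry called 2 lists at 3 days, 3 at 6 days and 0 in the other contrasts, where its smallest adjusted p was 0.149 between 6 and 3 days and 0.099 for artemether. Named genes follow a rule set beforehand. It takes Arx, Gcg, Ins1, Ins2, Pdx1, Pax4, Mafb and Gphn, then the 10 called genes per direction with the largest change that move the same way in every clone or have no overlap between arms. It adds up to 4 members of each list described, called members first and then the most expressed. Unnamed gene models and pseudogenes were left out.

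Tested on simulated data, limma recovered 85.6% of changes of 1 log2 unit and 98% of 2 log2 units in the 3-day comparison of 11172 genes. In the artemether comparison of 10993 genes it recovered 34.4% of changes of 1 log2 unit and 70.8% of 2. Each simulated change had the same size in every clone or repeat, with independent noise, unlike the data, in which clone 17 moved little. These shares therefore do not apply to changes that differ between clones. Alternatives were median-of-ratios and quantile scaling, a pseudocount of 0.1, no filter, a filter at a mean of 2 RPKM, the mean over transcript rows, other blocks, fits on the compared groups alone, and leaving out each clone or alpha-TC1 library. Quantile scaling, the filter at 2 RPKM, the transcript mean, the alpha identity list without Arx, the chaperone list without Hsp90b1, the clone 17 slope without Hsp90b1 and Rpl41, and sets from the 6-day contrast without clone 17 were chosen after seeing the data. The count-based alternatives planned at first were not run, since no counts were used. The lists mt_encoded, ARX_targets_brain and mesenchyme had too few members tested in both lines. So did acinar and immune in Min6-ARX, and other_islet_hormones and duct_progenitor in alpha-TC1. Lists of markers for blood, stromal, liver and neural cells were written after immune transcripts had been seen in 1 library.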

Results

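The data comprise 9 Min6-ARX libraries (clones 9, 16 and 17 at 0, 3 and 6 days of doxycycline, n = 3 per time) and 4 alpha-TC1 libraries (DMSO and 10 µM artemether, n = 2 each). Arx is a homeodomain transcription factor of alpha cells, and artemether is an antimalarial artemisinin. Expression is given in RPKM as mean ± SD, and changes are differences of log2(RPKM + 1). Depth was 18670000 to 25410000 reads per library, at which 1 read on a transcript of 1 kb is worth about 0.0394 to 0.0536 RPKM.

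The switched gene was read out in every Min6-ARX library. Arx (chromosome X, 93286445 to 93298357, GRCm38) went from 0.87 RPKM without doxycycline to 12.4 at 3 days and 18.6 at 6 days in clone 9, and from 1.24 to 18.0 and 26.9 in clone 16. In clone 17 it went from 0.30 to 2.57 and 3.46. Thus Arx was higher with doxycycline in all 3 clones, and clone 17 reached the lowest level at each time. The transgene and the endogenous gene cannot be separated in these values.

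The comparison of 3 days with no doxycycline asked what early Arx induction changes in these beta-like cells. Cholesterol synthesis genes fell together, a list call that was lost with an estimated correlation (adjusted p = 0.756 with an estimated correlation). Of 21 list members for cholesterol synthesis and its control, 20 were called lower over all genes (21 adjusted over the list alone), with a median log2 change of -0.90. Hmgcs1, an early enzyme of the pathway (chromosome 13, 119690379 to 119708260), fell from 68.8 ± 10.3 to 28.8 ± 2.78 RPKM (log2 change -1.22, SE 0.15, adjusted p = 0.0271). Its transcript was lower in each clone. Lss fell from 36.0 ± 4.36 to 19.1 ± 4.91, Dhcr7 from 31.5 ± 1.27 to 17.9 ± 2.70, and Srebf2, the transcription factor that controls the pathway, from 32.2 ± 1.26 to 19.0 ± 2.22. Camera called the list (adjusted p = 3.76e-21) with the preset correlation, as did fry (adjusted p = 0.0375). The median change of the list was -1.21 in clone 9, -0.85 in clone 16 and -0.65 in clone 17.

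Ppy, which encodes pancreatic polypeptide (chromosome 11, 102099930 to 102101319), rose from 46.5 ± 71.0 to 151 ± 128 RPKM (log2 change 2.80, SE 0.43, adjusted p = 0.0354). The spread reflects clone 17, where Ppy was already at 129 RPKM without doxycycline against 4.85 and 6.22 in clones 9 and 16. Of 9 islet hormone genes in the list that holds Ppy, 1 was called higher and 1 lower over all genes (2 and 2 adjusted over the list alone), and camera did not call the list (median 0.02, adjusted p = 0.979). Arx itself rose by 2.46 (SE 0.32, adjusted p = 0.0271). The other rising genes with the largest changes were Rflna (1.79), the protease gene Napsa (1.69), the cholesterol exporter Abca1 (1.69), the receptor gene Gprc5c (1.55), Cib3 (1.51), Cpt1a, which brings fatty acids into mitochondria (1.30), the alcohol dehydrogenase Adh1 (1.20) and Drc1 (1.19). Among the largest falls were Npy, encoding neuropeptide Y (-1.83), Pcsk9 (-1.58), the desaturase Scd1 (-1.35), Fdps (-1.34), Cyp51 (-1.26), Qsox1 (-1.23), Insig1 (-1.21), Idi1 (-1.20) and the prolactin receptor Prlr (-1.18).

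Genes of beta cell identity moved in both directions, with 1 of 18 called higher and 1 called lower (1 and 2 adjusted over the list alone). The zinc transporter Slc30a8 rose from 139 ± 29.1 to 233 ± 73.7 RPKM, and Prlr fell. Ins2 stood at 59408 ± 9439 without doxycycline and 54289 ± 8754 at 3 days, and Pdx1 at 118 ± 9.48 and 72.1 ± 24.4 (adjusted p = 0.0628), neither past the threshold. Gcg, encoding glucagon, was at 338 ± 264 and 176 ± 45.0, Ins1 at 2198 ± 249 and 1768 ± 814, Pax4 at 2.32 ± 0.61 and 3.82 ± 0.54, and Gphn, the inhibitory synapse scaffold, at 21.7 ± 2.87 and 22.3 ± 1.52. Mafb averaged at most 0.20 RPKM at each time and was not tested. In the granule list Syt7 (log2 change 0.96) and Pcsk1n (0.66) rose and Vgf (-1.06) fell. Among 14 genes of GABA signalling, the receptor subunit Gabra4 fell from 10.8 ± 2.20 to 6.09 ± 0.36, and 1 gene rose and 2 fell adjusted over the list alone.

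Camera also called falls in the cell cycle (median -0.63, 26 of 30 lower adjusted over the list alone), ER chaperone (-0.84, 16 of 17), ATF4 stress response (-0.40, 7 of 18) and oxidative phosphorylation (-0.10, 0 of 30) lists. It called rises in the p53 (0.42, 3 of 12), interferon (0.38, 4 of 8) and ion channel (0.31, 2 of 15) lists. Each call was lost with an estimated correlation (adjusted p = 0.756 with an estimated correlation for each). Of all their members, Atf4 (260 ± 41.9 to 158 ± 52.4 RPKM) passed over all genes. The chaperone Hspa5 was at 1180 ± 25.4 without doxycycline and 704 ± 411 at 3 days, and Calr at 1193 ± 117 and 772 ± 384. Hsp90b1, named after its values were seen, was at 1.45, 1.38 and 1101 RPKM in clones 9, 16 and 17 without doxycycline and at 526, 463 and 1.48 at 3 days, and without it the chaperone list had a median of -0.86 (camera adjusted p = 9.70e-09, adjusted p = 0.756 with an estimated correlation). Chaperone medians were -1.17 in clone 9 and -1.33 in clone 16 but 0.03 in clone 17, and cell cycle medians were -0.62, -1.33 and 0.02. Top2a, a replication enzyme, was at 124 ± 20.8 and 84.2 ± 45.6 RPKM. The ATF4 list differed between clones too, at -0.95, 0.10 and -0.38. Without clone 9 the ion channel (adjusted p = 0.105), interferon (0.075) and oxidative phosphorylation (0.552) calls were lost, and without clone 16 the p53 (0.105) and oxidative phosphorylation (0.139) calls. The interferon call was also lost without the clone block (adjusted p = 0.0521), and the oxidative phosphorylation call with quantile scaling (adjusted p = 0.99).

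In all, limma called 76 genes higher and 66 lower of 11172, and each moved the same way in all 3 clones. Without the clone block it called 0 and 0 (3437 genes had an unadjusted p under 0.05 in the blocked fit). The calls depend on the clones: without clone 9 there were 0 and 0, without clone 16 there were 2 and 0, and without clone 17 there were 3067 and 2405; without the filter on low values, or with the 6 compared libraries alone, there were 0 and 0.

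**Figure D1:**
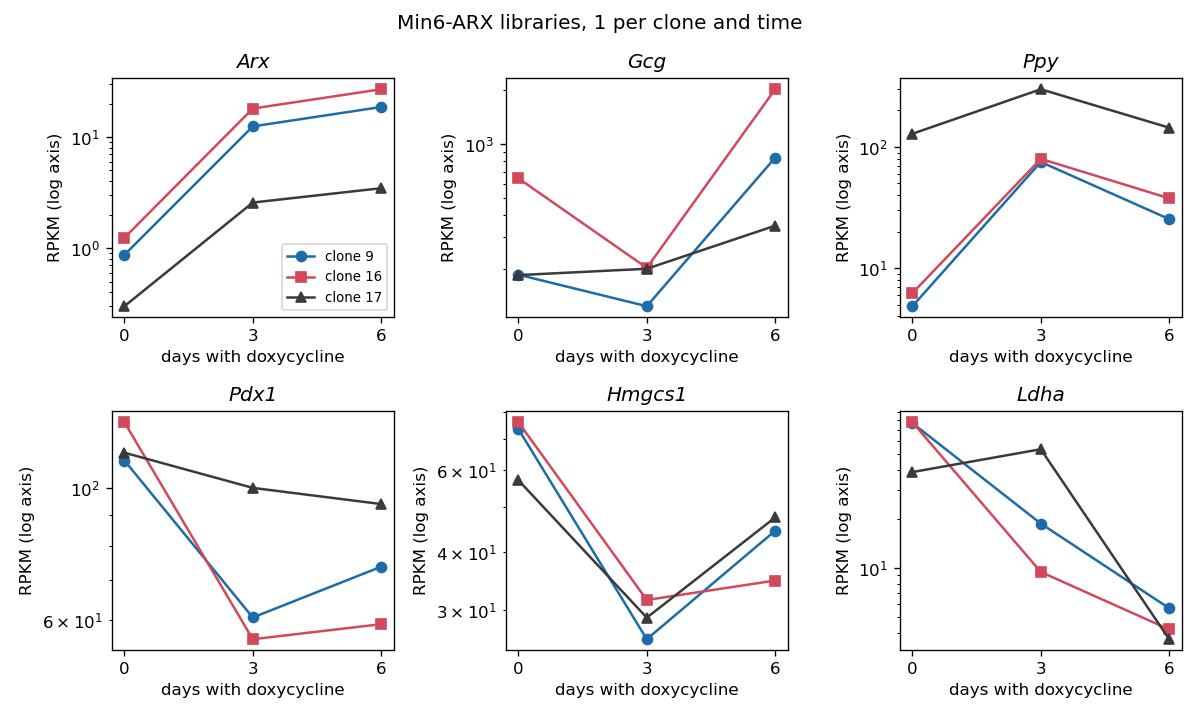
RPKM (log axis) of 6 genes against days of doxycycline, with 1 point per library and a line per clone. Arx in clone 17 reached 3.46 RPKM at 6 days against 18.6 and 26.9 in clones 9 and 16, while Ldha was at 3.65 to 5.65 in all 3 clones.

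The 6-day comparison asked what longer induction changes. Alpha cell genes rose as a group, and the lists of cholesterol synthesis, the cell cycle, the ATF4 stress response, glycolysis and the hypoxia response fell. All 6 list calls were lost with an estimated correlation (adjusted p = 0.308, 0.387, 0.482, 0.439, 0.439 and 0.308 with an estimated correlation, in that order), and of the 9 alpha cell genes 0 were called over all genes. Tspan8, which encodes a tetraspanin membrane protein (chromosome 10, 115816832 to 115849893), rose from 2.01 ± 0.67 to 6.94 ± 2.08 RPKM (log2 change 1.38, SE 0.12, adjusted p = 0.016) and was the 1 gene called. Arx stood just outside the threshold (0.80 ± 0.47 to 16.3 ± 11.9 RPKM, log2 difference 2.94, adjusted p = 0.050029). Gcg was at 338 ± 264 RPKM without doxycycline and 1072 ± 863 at 6 days (log2 difference 1.58, SE 0.40, adjusted p = 0.158). It went from 186 to 839 RPKM in clone 9, from 643 to 2027 in clone 16 and from 185 to 349 in clone 17.

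Of 9 tested alpha identity genes 8 were higher, 5 of them past the threshold adjusted over the list alone and 0 over all genes (median log2 change 0.48, camera adjusted p = 4.13e-05, adjusted p = 0.308 with an estimated correlation). The list holds Arx, which the design switches on. Without Arx 7 of 8 were higher, 3 of them past the threshold adjusted over the list alone (median 0.47, camera adjusted p = 0.000883, adjusted p = 0.376 with an estimated correlation). The amino acid transporter Slc38a5 was at 1023 ± 268 RPKM without doxycycline and 1384 ± 199 at 6 days, Ttr at 2494 ± 1166 and 3058 ± 1753, and Etv1 at 59.1 ± 6.10 and 73.4 ± 16.6. The beta identity list fell (median -0.18, 0 of 18 called over all genes and 4 lower adjusted over the list alone, camera adjusted p = 0.00601, adjusted p = 0.482 with an estimated correlation). Iapp, the gene of islet amyloid polypeptide, was at 21912 ± 1822 and 13727 ± 6322, Ins1 at 2198 ± 249 and 1578 ± 278, Ins2 at 59408 ± 9439 and 53953 ± 6318, and G6pc2 at 594 ± 61.0 and 556 ± 103. Pdx1 was at 118 ± 9.48 and 75.6 ± 17.6, Pax4 at 2.32 ± 0.61 and 1.31 ± 0.74, and Gphn at 21.7 ± 2.87 and 18.7 ± 5.01.

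The list of genes normally kept low in beta cells fell (median -0.21, 0 of 12 called over all genes and 2 lower adjusted over the list alone, camera adjusted p = 0.0189, adjusted p = 0.308 with an estimated correlation). It holds Ldha, the lactate dehydrogenase subunit, at 64.5 ± 22.4 RPKM without doxycycline and 4.497 ± 1.035 at 6 days (log2 difference -3.52, SE 0.51, adjusted p = 0.0747). Oat was at 58.8 ± 11.6 and 36.8 ± 22.6, and Dap at 110 ± 10.4 and 97.2 ± 5.91. That list call was lost without clone 17 (adjusted p = 0.0878), without the clone block (adjusted p = 0.0611) and with the transcript mean (adjusted p = 0.0621). Glycolysis genes fell (median -0.20, 5 of 17 lower adjusted over the list alone, camera adjusted p = 0.000462, adjusted p = 0.439 with an estimated correlation), with Gapdh at 910 ± 106 and 701 ± 24.7 and Pgk1 at 257 ± 8.85 and 187 ± 25.4. Hypoxia genes fell (median -0.34, 7 of 12 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.308 with an estimated correlation), with Bnip3 at 38.9 ± 2.84 and 22.5 ± 1.11 and Vegfa at 86.8 ± 11.2 and 65.7 ± 15.2. Hypoxia medians were -0.44, -0.28 and -0.25 in clones 9, 16 and 17.

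Cholesterol genes were lower in 21 of 21 cases (median -0.57, 21 adjusted over the list alone and 0 over all genes, camera adjusted p = 6.21e-16, adjusted p = 0.387 with an estimated correlation), with Fdps at 143 ± 19.9 and 80.7 ± 26.6 RPKM and Hmgcr, the rate-limiting enzyme, at 81.9 ± 7.66 and 58.2 ± 12.0. The ATF4 list fell (median -0.69, 13 of 18 lower adjusted over the list alone, camera adjusted p = 1.69e-07, adjusted p = 0.439 with an estimated correlation), with Asns at 210 ± 35.8 and 141 ± 73.8 and Psat1 at 156 ± 45.6 and 103 ± 63.7. Cell cycle genes fell (median -0.54, 9 of 30 lower adjusted over the list alone, camera adjusted p = 2.32e-11, adjusted p = 0.482 with an estimated correlation), with Pcna at 301 ± 25.9 and 224 ± 59.8. Their medians were -0.55, -0.99 and -0.03 in clones 9, 16 and 17. Camera also called the oxidative phosphorylation list lower (-0.16) and the p53 (0.37), ion channel (0.18), interferon (0.15) and duct or progenitor (0.35) lists higher. These were lost with an estimated correlation (adjusted p = 0.634, 0.522, 0.634, 0.62 and 0.308 with an estimated correlation). In the last, Krt7 was at 98.9 ± 19.9 and 141 ± 25.4. Without clone 16 the oxidative phosphorylation (adjusted p = 0.135), p53 (0.0591) and ion channel (0.0675) calls were lost, and without clone 17 the interferon (0.243) and duct or progenitor (0.123) calls. Without the clone block the interferon (adjusted p = 0.0622) and duct or progenitor (0.0655) calls were lost, as they were with no filter (0.218 and 0.0823). Quantile scaling ended the oxidative phosphorylation (adjusted p = 0.355) and interferon (0.0946) calls, and the transcript mean the interferon call (0.052).

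At 6 days limma called 1 gene higher and 0 lower, with 2166 at an unadjusted p under 0.05. Without clone 17 it called 1747 and 1962, without clone 9 or clone 16 it called 0 and 0, and without the clone block or the filter it called 0 and 0. The 6 compared libraries alone gave 1 and 2 calls.

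**Figure D2:**
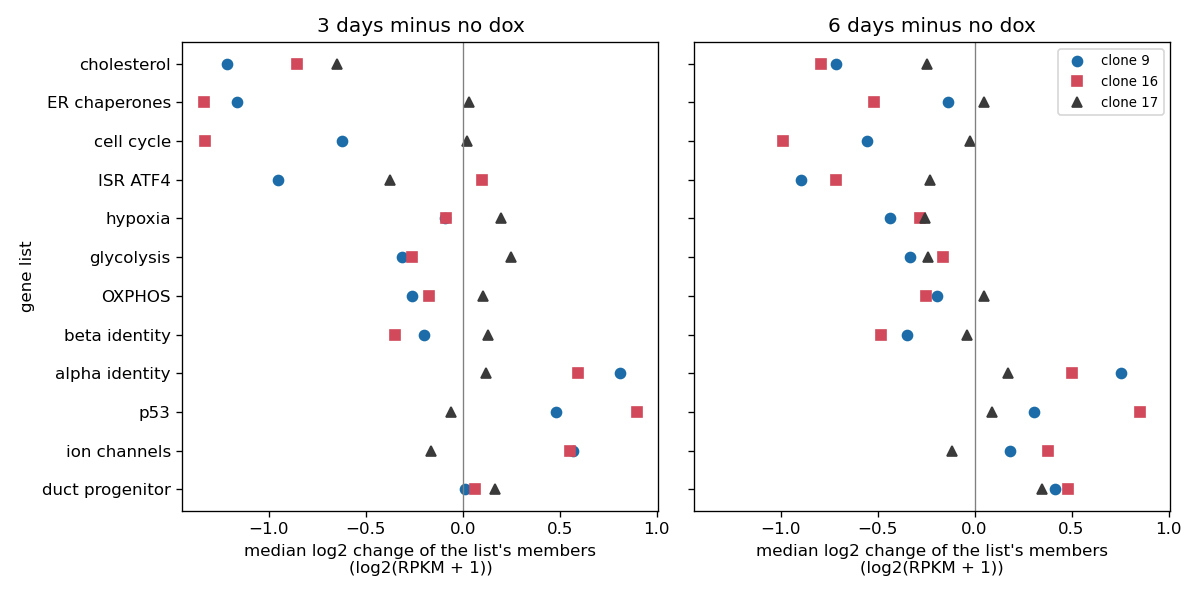
Median log2 change of the members of 12 gene lists at 3 and 6 days against no doxycycline, with 1 point per clone. At 3 days the ER chaperone median was -1.17 and -1.33 in clones 9 and 16 and 0.03 in clone 17.

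Between 3 and 6 days of doxycycline, ER chaperone and cholesterol genes rose as lists and glycolysis genes fell. All 3 calls were lost with an estimated correlation (adjusted p = 0.731, 0.731 and 0.783 with an estimated correlation). All 17 chaperone genes were higher at 6 days (median log2 change 0.62, 0 called over all genes and 0 adjusted over the list alone, camera adjusted p = 4.11e-08, adjusted p = 0.731 with an estimated correlation). Hspa5 was at 704 ± 411 RPKM at 3 days and 1078 ± 187 at 6 days, Calr at 772 ± 384 and 1073 ± 173, and Pdia6 at 415 ± 334 and 653 ± 212. All 21 cholesterol genes were higher (median 0.32, 0 adjusted over the list alone, camera adjusted p = 4.18e-09, adjusted p = 0.731 with an estimated correlation), with Hmgcr at 43.2 ± 3.11 and 58.2 ± 12.0 and Fdps at 57.7 ± 20.4 and 80.7 ± 26.6. Glycolysis genes fell (median -0.24, 4 of 17 lower adjusted over the list alone, camera adjusted p = 0.0182, adjusted p = 0.783 with an estimated correlation), with Aldoa at 402 ± 43.9 and 310 ± 42.7 and Pkm at 587 ± 20.1 and 509 ± 64.9.

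Gcg was at 176 ± 45.0 RPKM at 3 days and 1072 ± 863 at 6 days (log2 difference 2.29, SE 0.40, adjusted p = 0.115), higher in 3 of 3 clones. Pax4 was at 3.82 ± 0.54 and 1.31 ± 0.74 (log2 difference -1.10, adjusted p = 0.116), Arx at 11.0 ± 7.82 and 16.3 ± 11.9, Pdx1 at 72.1 ± 24.4 and 75.6 ± 17.6, Ins1 at 1768 ± 814 and 1578 ± 278, Ins2 at 54289 ± 8754 and 53953 ± 6318, and Gphn at 22.3 ± 1.52 and 18.7 ± 5.01. By limma 0 genes were called in either direction, and 2258 had an unadjusted p under 0.05. Without clone 17, 1181 were called higher and 1911 lower, and the glycolysis call was lost (adjusted p = 0.488).

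Tspan8 was called higher at both 3 days (log2 change 0.68, adjusted p = 0.0429) and 6 days. This is 1 shared higher call, where independent lists of 76 and 1 among 11172 genes would share 0.0068, and 0 shared lower calls, where 0 would be shared. Across genes the log2 changes at 3 and 6 days correlated at 0.667 with a covariance of 0.0526. In 50 simulations with no change, both times were set against the same simulated no-doxycycline libraries. The mean correlation was 0.484 (highest 0.604), the mean covariance 0.0107 (highest 0.0159) and the mean number of shared calls 0. Since no gene was simulated as changed, that last value is no reference for the overlap of real changes. The controls are too few to split, so part of the excess of shared calls over independent lists may come from the shared controls. They add the same covariance with or without a real change. Without clone 17 there were 2559 shared calls, 1261 higher and 1298 lower, where independent lists would share 484 and 426, and 92 genes were called in opposite directions. With an adjusted p under 0.01, with no clone block, or without clone 9 or 16 there were 0.

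In alpha-TC1 cells the artemether comparison asked how the drug changes the alpha cell transcriptome. Transcripts of glycolysis, the hypoxia response and ER chaperones were lower with artemether as lists. All 3 calls were lost with an estimated correlation (adjusted p = 0.77, 0.77 and 0.809 with an estimated correlation). Gcg was at 1491 ± 459 RPKM in DMSO and 2624 ± 358 in artemether (n = 2 each). The Gcg log2 difference was 0.84 (SE 0.25, adjusted p = 0.223). Mafb, a transcription factor of alpha cells (chromosome 2, 160363703 to 160367065), was at 11.1 ± 0.76 and 6.11 ± 0.10 (log2 difference -0.76, SE 0.10, adjusted p = 0.104). Arx was listed at 0.017 and 0.0001 RPKM in the DMSO libraries and 0.0001 and 0.016 in the artemether libraries, at or below the level of 1 read, and Pax4 was listed at 0.0001 in all 4. A fall of Arx was therefore not detectable at this depth, and no rise above the level of 1 read was seen with artemether. Gphn was at 17.6 ± 1.13 and 17.9 ± 1.10, Ins1 at 5.56 ± 0.47 and 6.04 ± 0.29, and Ins2 at 50.03 ± 5.69 and 53.8 ± 3.88.

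Glycolysis genes fell as a list (median log2 change -1.55, 15 of 17 lower and 1 higher adjusted over the list alone, 0 over all genes, camera adjusted p = 1.14e-16, adjusted p = 0.77 with an estimated correlation). Gapdh was at 2966 ± 131 RPKM in DMSO and 1132 ± 150 in artemether, Aldoa at 1662 ± 154 and 503 ± 46.5, Pgk1 at 1526 ± 197 and 506 ± 69.5, and Tpi1 at 1494 ± 265 and 514 ± 56.1. Hypoxia genes fell (median -1.46, 14 of 14 lower adjusted over the list alone, camera adjusted p = 4.37e-16, adjusted p = 0.77 with an estimated correlation). Bnip3, a mitophagy gene, was at 244 ± 107 and 22.5 ± 1.45, P4ha2 at 98.8 ± 13.4 and 25.9 ± 3.74, Ndrg1 at 111 ± 14.3 and 54.3 ± 8.41, and Higd1a at 94.4 ± 31.6 and 44.4 ± 4.71.

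ER chaperones fell (median -1.50, 11 of 17 lower adjusted over the list alone, camera adjusted p = 2.03e-10, adjusted p = 0.809 with an estimated correlation). Hspa5 was at 1257 ± 864 RPKM in DMSO and 216 ± 5.67 in artemether, Calr at 1085 ± 619 and 280 ± 15.1, Hsp90b1 at 1184 ± 645 and 385 ± 8.93, and Pdia3 at 469 ± 219 and 204 ± 6.79. The DMSO libraries differed from each other by a median of 1.23 log2 units in this list, repeat 1 being higher, and by -0.64 in the hypoxia list, repeat 2 being higher. The ATF4 list also fell (median -0.54, 1 of 17 lower and 1 higher adjusted over the list alone, camera adjusted p = 3.81e-05, adjusted p = 0.847 with an estimated correlation), with Ddit3 at 491 ± 324 and 119 ± 8.21. Its members differed between DMSO repeats 1 and 2 too, among them Ddit3 (720 and 262 RPKM), Atf4 (482 and 332), Herpud1 (282 and 150) and Asns (312 and 236). Cytosolic and mitochondrial heat shock genes fell (median -0.41, 7 of 9 lower adjusted over the list alone, camera adjusted p = 5.45e-07, adjusted p = 0.77 with an estimated correlation), with Hspa8 at 1387 ± 39.6 and 1045 ± 18.7 and Hspe1 at 277 ± 31.1 and 174 ± 18.1. Cholesterol genes had a median of -0.23 (3 of 20 lower adjusted over the list alone, camera adjusted p = 0.000276, adjusted p = 0.847 with an estimated correlation), with Insig1 at 140 ± 14.5 and 83.5 ± 10.8. The oxidative phosphorylation list had a median of -0.09 (0 of 30 adjusted over the list alone, camera adjusted p = 0.0128, adjusted p = 0.847 with an estimated correlation). Camera turned that direction under quantile scaling (median -0.0022, adjusted p = 0.459), and the call was lost without DMSO repeat 2 (adjusted p = 0.307) or artemether repeat 1 (adjusted p = 0.31).

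Interferon genes rose as a list (median 0.69, 0 of 8 adjusted over the list alone, camera adjusted p = 0.0179, adjusted p = 0.847 with an estimated correlation), with Stat1 at 12.9 ± 0.46 RPKM in DMSO and 20.3 ± 6.62 in artemether. Artemether repeat 1 held transcripts of immune cells that were near 0 in the other 3 libraries, and its interferon median against DMSO was 0.89, against 0.35 in repeat 2. The antigen presentation gene Cd74 was at 646 RPKM there and at most 0.946 elsewhere. The immune list had a median of 5.63 in repeat 1 and 0.02 in repeat 2. Without that library the interferon call was lost (adjusted p = 0.172), as it was without DMSO repeat 1 (adjusted p = 0.0562). The glycolysis, hypoxia and ER chaperone medians were -1.65, -1.49 and -1.53 in repeat 1 and -1.45, -1.43 and -1.48 in repeat 2. Of the granule list, which was not called, Chga was at 620 ± 84.4 and 967 ± 113, and of GABA signalling genes Gabrb3 was at 21.4 ± 0.94 and 25.9 ± 5.08.

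By limma 0 genes were called in either direction of 10993, and 2033 had an unadjusted p under 0.05. The artemether repeats differed from each other by over 2-fold in 593 genes (SD of log2 differences 0.781). The DMSO repeats did so in 47 (SD 0.249). This spread, which includes the immune transcripts of artemether repeat 1, enters the test, so the count of 0 does not show a lack of change. The smallest adjusted p was 0.0622, for genes including Hspa1a, P4ha1 and Sncb, which were named after their values were seen. Hspa1a was at 17.3 ± 4.29 and 0.33 ± 0.13 RPKM, P4ha1 at 51.7 ± 8.65 and 9.31 ± 0.10, and Sncb at 120 ± 13.4 and 26.9 ± 2.76. Fits without 1 library left 1 library in an arm, so their counts are not given. Without artemether repeat 2, the artemether arm was repeat 1 alone, in which 572 genes reached 1 RPKM while staying under 0.1 in the other libraries. A pseudocount of 0.1 gave 8 genes higher and 77 lower.

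**Figure D3:**
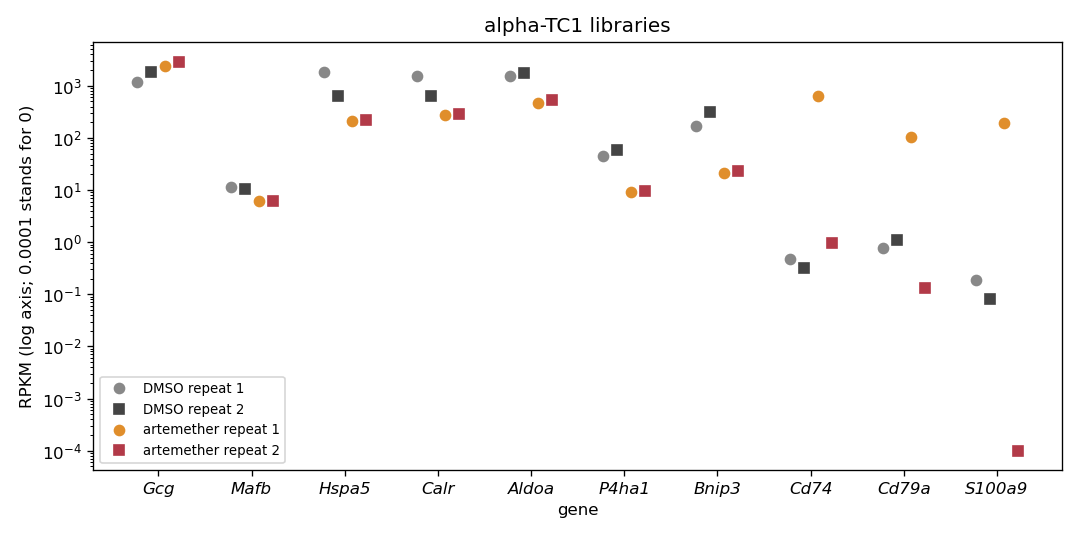
RPKM (log axis) of 10 genes in the 4 alpha-TC1 libraries, with 1 point per library. Hspa5, Aldoa and Bnip3 were lower in both artemether libraries, while Cd74, at 646 RPKM in artemether repeat 1, was at most 0.946 in the others.

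Genes called with doxycycline in Min6-ARX were then looked up in the artemether comparison. The 6-day calls (1 higher and 0 lower) were too few for a set test. Across 9880 genes tested in both lines, which are not independent replicates, the log2 changes at 6 days and with artemether had a Spearman correlation of 0.19. It was 0.11 without artemether repeat 1 and 0.23 without artemether repeat 2, ranged from 0.02 to 0.26 over the 12 pairings of an artemether library, a DMSO library and a clone, and was 0.28 with the 3-day changes. The 53 genes called higher at 3 days and tested in alpha-TC1 had a median log2 change of 0.34 with artemether (camera p = 0.000449, p = 0.298 with an estimated correlation), and the 51 called lower had -0.03 (p = 0.0773, p = 0.663 with an estimated correlation). The median of the higher set stayed above 0 when 1 alpha-TC1 library was left out (0.23 to 0.42). That of the lower set turned to 0.10 without artemether repeat 1 and 0.08 without DMSO repeat 2, and was -0.17 without DMSO repeat 1 or artemether repeat 2.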

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

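Tests of the Arx level, of the clone 17 time labels, of its slope without 2 genes, of blood RNA, of the culture state and of what the artemether libraries share were chosen after the result was seen; the slope of clone 17, the scaling test and the counts of other splits were set before.

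3 gene lists differed in their effect between 3 and 6 days, tested as the difference itself by camera with a preset correlation. The median difference in log2 change, 6 days minus 3 days, was 0.616 for ER chaperones (adjusted p = 4.11e-08, higher in 17 of 17 genes), 0.317 for cholesterol genes (adjusted p = 4.18e-09, 21 of 21) and -0.24 for glycolysis genes (adjusted p = 0.0182, lower in 14 of 17). All 3 calls were lost with an estimated correlation (adjusted p = 0.731, 0.731 and 0.783 with an estimated correlation). By clone, the chaperone difference was 1.031, 0.78 and 0.01 in clones 9, 16 and 17, the cholesterol difference 0.57, 0.06 and 0.36, and the glycolysis difference -0.24, -0.10 and -0.37.

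Over 5443 genes called at 3 days without clone 17, its log2 changes had a slope of 0.039 on the mean of clones 9 and 16. The 95% bootstrap interval over genes was -0.0345 to 0.0835. Genes are not independent, so the intervals given here leave out the spread between clones or libraries. Hsp90b1 and Rpl41 were then left out, picked after their values were seen because these jumped between low and high. Without them the slope was 0.0737 (0.0617 to 0.0852) at 3 days and 0.117 (0.096 to 0.144) at 6 days, or 0.132 and 0.236 over the genes past 2-fold in that mean. At 3 days clone 16 on clone 9 had 0.941 over the 331 genes past 2-fold in clone 9, and clone 9 on clone 16 had 0.757 over the 540 past 2-fold in clone 16, while clone 17 moved the same way in 68% and 64.6% of these genes, and at 6 days in 79% and 70.3% of 119 and 256 genes chosen alike. Slopes this far from 1 argue against doxycycline itself, acting alike in every clone, as the source of the changes in clones 9 and 16 over these genes as a set, but not for lists in which clone 17 moved with clones 9 and 16, among them cholesterol at 3 days (median -0.65 against -1.21 and -0.85) and, at 6 days, hypoxia (-0.25 against -0.44 and -0.28), glycolysis (-0.24 against -0.33 and -0.16), duct or progenitor genes (0.35 against 0.41 and 0.48) and genes kept low in beta cells (-0.15 against -0.24 and -0.23), which include Ldha. An exchange of the no-doxycycline label within clone 17 is argued against by Arx, 11.5-fold higher at 6 days and 8.57-fold at 3 days, and an exchange of the 3-day and 6-day labels, as the source of the small slope, by a slope of 0.0292 of its 6-day changes on the 3-day mean of the other clones. A lower Arx level stays open: at 6 days Arx in clone 17 was 0.152 of the mean of the other clones, but with 1 such clone it cannot be told apart from other differences between clones.

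In artemether repeat 1, of the markers of B cells, T or NK cells, myeloid cells and erythroid cells, a share of 0.789 was at least 10 times higher than in any other alpha-TC1 library, among them S100a9 at 192 RPKM, Hba-a1 at 159 and Cd79a at 105, and Xist was at 13.2 against at most 0.02. Induction by artemether is argued against by repeat 2, where a share of 0.0263 of these markers was above 2 times the highest DMSO library (on RPKM + 0.1), and a library of another cell type by alpha identity genes, whose median was only -0.229 log2 units from repeat 2. Admixed RNA of blood or lymphoid cells may be the source. The test set for it asked for most markers of each lineage. It was met for B cells (9 of 10), T or NK cells (8 of 9) and myeloid cells (10 of 10). Erythroid cells fell short with 3 of 9, which were Hba-a1, Hbb-b1 (113.7 RPKM) and Alas2 (20.35 RPKM). The test as set thus stays undecided because of the erythroid markers alone. Markers of fibroblasts or endothelium, liver and neural cells passed in 1 of 10 each (Pecam1, Hp and Nrgn). In the other 3 libraries 1 of the T or NK markers, 4 of the liver and 4 of the neural markers averaged at least 1 RPKM, and 0 of the other lists.

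The falls in ER chaperone, hypoxia and glycolysis transcripts with artemether covered 48 genes. Dilution by blood RNA is argued against by repeat 2, where their median against DMSO was -1.47, and scaling by a few abundant genes by a median of -1.55 under median-of-ratios scaling. The culture state of the DMSO wells stays open, as the DMSO libraries differed from each other, repeat 1 minus repeat 2, by 1.23 log2 units in the chaperone list; in the hypoxia and glycolysis lists the differences were -0.64 and -0.28, against changes of -1.46 and -1.55 with artemether. With 2 wells per arm it cannot be told apart from an effect of the drug, which is the biological explanation the design names.

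Other splits of the 6 libraries into groups of 3 were too few (10) for a share under 0.05. At 3 days the real split gave 142 genes and the highest other split 0, and 1 of 10 splits gave as many. At 6 days the real split gave 1 gene and the highest other 0, with 1 of 10 as large. Between 6 and 3 days all 10 splits gave 0. Among the 4 splits that part every clone pair, the highest other was 0 in each comparison.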

How the results depend on the processing

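Quantile scaling, the filter at 2 RPKM, the transcript mean, the alpha identity list without Arx, the chaperone list without Hsp90b1 and the 6-day changes without clone 17 were chosen after seeing the data. At 3 days the counts of 76 higher and 66 lower became 0 and 0 with no filter, with no replicate block and with the compared groups alone, and ranged from 0 to 3067 higher and 0 to 2405 lower without 1 clone. At 6 days the 1 higher gene became 2 with quantile scaling, a pseudocount of 0.1 or the transcript mean and 0 with no filter or no replicate block, the compared groups alone gave 2 lower, and leaving out a clone gave 0 to 1747 higher and 0 to 1962 lower. Between 6 and 3 days leaving out a clone gave 0 to 1181 higher and 0 to 1911 lower. With artemether, counts of 0 and 0 became 8 higher and 82 lower with quantile scaling, 8 and 77 with a pseudocount of 0.1 and 39 lower with the filter at 2 RPKM, and leaving out a library gave 0 to 655 higher and 0 to 31 lower. The shared 3-day and 6-day calls went from 1 to 0 at an adjusted p under 0.01 or with no block, and to 0 to 2559 without 1 clone. The correlation of 6-day and artemether changes was 0.19, moved to 0.28 with the 3-day changes and to 0.11 to 0.23 without 1 alpha-TC1 library. With artemether, camera turned the direction of the oxidative phosphorylation list to higher under quantile scaling (median -0.0022, adjusted p = 0.459). Over all settings, list medians kept direction and side of the threshold in 327 cases, lost the call in 59 and had camera's direction turned in 1, and named genes kept both in 703 cases, lost the call in 116 and gained a call in 67. The cause was not tested. Leaving out libraries or the other groups leaves fewer degrees of freedom, which does not explain the higher counts without clone 17. The log2 changes of that clone had the smallest SD at 3 days (0.213, against 0.435 in clone 9 and 0.484 in clone 16). An alpha-TC1 arm left with 1 library is assumed to vary like the other arm. Whether the repeat numbers of alpha-TC1 pair its libraries could not be told. With 2 libraries per arm, the correlation of deviations takes the same size for equal (-0.00378) and unequal numbers (0.00378). The artemether repeats also differed from each other more (SD of log2 differences 0.781) than the DMSO repeats (0.249). A replicate block left 0 and 0 calls. Sets called at 3 days at an adjusted p under 0.01 held too few genes to test, and count-based alternatives were not run. For Arx, listed at or below the level of 1 read in every alpha-TC1 library, a fall is beyond the depth, while no rise above that level was seen.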

Other observations

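The 3 genes given here were picked after their values were seen and did not pass the threshold over all genes at 6 days or with artemether. Slc16a3, the lactate exporter, was at 9.15 ± 1.19 RPKM without doxycycline and 1.13 ± 1.29 at 6 days in Min6-ARX (n = 3), and at 65.3 ± 46.4 in DMSO and 4.34 ± 0.53 in artemether in alpha-TC1 (n = 2). Ldha at 6 days was at 5.65, 4.19 and 3.65 RPKM in clones 9, 16 and 17, against 77.0, 78.0 and 38.6 without doxycycline. At 3 days Ldha was at 53.3 RPKM in clone 17 and at 18.7 and 9.43 in clones 9 and 16. In alpha-TC1 Ldha was at 5.51 and 8.63 in DMSO and at 23.3 and 0.658 in artemether repeats 1 and 2, so the artemether repeats lay on opposite sides of DMSO. Repeat 1 is the library that held immune cell transcripts, so its higher Ldha value cannot be assigned to the drug. The cytokine gene Mif was at 174 ± 16.4 and 76.0 ± 21.7 in Min6-ARX at 0 and 6 days, and at 1081 ± 58.7 and 254 ± 34.5 in alpha-TC1 with DMSO and artemether.

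In Min6-ARX the listed values of 2 genes, picked after their values were seen, jumped between low and high. Hsp90b1 was listed at 1.45, 526 and 891 RPKM at 0, 3 and 6 days in clone 9 and at 1.38, 463 and 669 in clone 16. In clone 17 it was listed at 1101, 1.48 and 1.5. The ribosomal gene Rpl41 was listed at 2.25, 894 and 994 in clone 9, 2.36, 906 and 889 in clone 16, and 2.54, 4.59 and 3.38 in clone 17. Related values did not follow these jumps. The other 16 chaperone genes had a median log2 change of -0.86 at 3 days, and 0 of them rose. Hspa5 stayed at 1153, 1178 and 1226 RPKM in clone 17, and Rpl41 was at 545 to 607 in alpha-TC1. Whether the low values of Hsp90b1 and Rpl41 reflect expression was not tested, so they are not read as changes.

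The list of other islet hormones was not called at 3 days, at 6 days or between them (camera adjusted p = 0.979, 0.675 and 0.876). Of its members, Sst, encoding somatostatin, averaged 12.5 ± 9.45 RPKM without doxycycline, 4.78 ± 4.96 at 3 days and 2.41 ± 2.39 at 6 days, and was lower in 3 of 3 clones at both times without passing the test. Npy was at 561 ± 201, 192 ± 171 and 455 ± 243 at the 3 times, so its called fall at 3 days was followed by a higher mean at 6 days. Ppy was at 46.5 ± 71.0, 151 ± 128 and 69.1 ± 65.4. In alpha-TC1, 572 genes reached 1 RPKM in artemether repeat 1 while staying under 0.1 in the other 3 libraries, against 0 for artemether repeat 2 and 1 for each DMSO library.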
